A study of Mus musculus with 8 samples.

How the data were processed

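RNA from the ileum of female mice was measured on 8 Agilent mouse whole-genome arrays with 1 colour, 4 from doxycycline-injected and 4 from saline-injected animals, per the labels. The labels give 200 ng of RNA for labelling. All 8 arrays lie on 1 slide. The doxycycline arrays fill row 1 and the saline arrays row 2, so slide row and treatment cannot be told apart. The labels describe mice but do not state in so many words that each array holds a different animal, so p-values measure the spread between these samples.

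The deposited scanner files hold spot intensity on a linear scale, made with Agilent Feature Extraction 10.7.3.1 per the file headers and the submitters' processing notes. Per the file headers, the processed intensity is background-subtracted, detrended across the array, and replaced by a surrogate value where a spot does not rise above the noise. The deposited value table holds log2 values. Set against the scanner files, each of its columns equals the log2 processed intensity minus a constant, with the same direction and with no centring of genes, so none of scale, centring and direction stays unknown. The medians of its columns were -3.77, -3.92, -3.83 and -3.81 for doxycycline replicates 1 to 4, and -3.97, -3.70, -3.79 and -3.86 for saline replicates 1 to 4. The table served as an alternative only.

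Each array held 62976 spots, of which 59305 were probe spots for 55681 probes. Control spots and spots marked as outliers by the scanner software (169 to 259 per array) were left out, and spots of the same probe were averaged. No probe spot was saturated. Each array's log2 processed intensity was reduced by its own 75th percentile, and levels below are on this scale. A probe was kept when it was well above background on at least 4 of the 8 arrays, whatever their group, which left 28626 probes. A gene was represented by its kept probe with the highest mean level, giving 21362 genes tested out of 35715 names on the array. Gene names are those of the array design. Of the tested genes, 14514 have an accession in the RefSeq gene table (assembly GRCm38.p6), and for 685 of these the current symbol differs from the array's name. Probe positions are those of the array's mm9 annotation. No transcript annotation of that build was used here, so exons and untranslated regions are not given.

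Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of adjusted p 0.05. The 5′-side Tnk1 probe, which is not the brightest of its gene, was taken from the same fit over all 28626 kept probes. Single measures were compared with an exact two-sided permutation test, whose smallest possible p with 4 against 4 is 0.0286. Errors beside group means are SD with n = 4, and errors beside differences are SE. Gene lists for pathways and cell types were compared with limma's camera at a preset correlation of 0.01, two-sided, over the 60 lists with at least 5 tested members. Camera was repeated with an estimated correlation and beside fry, which asks whether a list's genes move, on balance, in a single direction. Of 1443 listed genes, 1405 were matched to the array and 1278 were tested. Lists can share genes, so their results are not independent. Among the named genes, Gdf15 is in the p53 and integrated stress response lists, and Pmaip1 in the p53 and apoptosis lists. Hdc is in the neutrophil and mast cell lists. A list of mitochondrially encoded proteins matched no array name and has no value here. For camera, 56 genes with a missing value were left out. Counts within a list are also given with the adjustment over the list alone.

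A gene not well above background on any array of a group has only a bound there. Its bound sets the bright group's mean against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal of any probe well above background, and is written as at least N-fold. These bounds hold for the scanner software's background subtraction only, and with normexp background Hdc, Il6, Il5ra and Oxct2b differed by less than theirs. Genes were named by a fixed rule. It takes Tnk1 and Hprt, then the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap, leaving out clone, predicted and sex-linked names. It also takes up to 4 tested members with the smallest p from each list past the threshold, and from the cell death, p53, NF-kB, interferon, tight junction, integrated stress response and mitochondrial lists in any case. Sex-linked names were taken as those of a fixed control list. Hprt, which lies on the X chromosome, is not on that list and counts among the 10 rises. Genes named beyond this rule are said to be chosen after their values were seen. Some genes that the rule takes are not reported here.

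The design, the lists, the rule for names and most alternatives were fixed before the data were examined. These alternatives were normexp background correction (offset 50), quantile and median scaling, other filters on dim probes, other ways of combining probes, a trended and robust eBayes, array weights, the replicate number as a block, the value table, other thresholds, and leaving out each array in turn. A common floor and the removal of saline replicates 2 and 4 together were added after the data were seen. In the common-floor setting, 3114 kept probes at the floor on every array were left out, a step also chosen after their values were seen.

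The fit was tested on simulated data for this comparison, with 21306 genes of which 200 were changed. It recovered 38 of 100 genes changed by log2 1 and 81 of 100 changed by log2 2, with 9 false calls among 135. A list of 22 further genes was lowered by log2 1. Of these, 7 were recovered, and it was the 1 list past the threshold. The simulated genes were drawn independently of each other. In the real data genes of a list move together (estimated correlation 0.69 for the interferon-stimulated list), so the simulation does not show how often a list passes by chance. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 and tables handled with pandas 2.3.3.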

Results

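The data are expression profiles of the mouse ileum, the last part of the small intestine, from a knock-in line in which TNK1 can be switched on. TNK1 is a non-receptor tyrosine kinase. The strain carries rtTA, a transcription activator that works only with doxycycline, at Rosa26, and a Myc-tagged Tnk1 transgene at the Hprt locus on the X chromosome. Doxycycline was injected at 50 µg per g in 100 µl, controls received 100 µl of 0.9% NaCl, and tissue was taken after 24 hours. There were 4 arrays per group. The comparison asks what changes in the gut when TNK1 is induced. The labels give the saline animals the transgenic strain but also a wild-type source name, and no group received doxycycline without the transgene.

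Tnk1 signal rose on the probe that lies toward the 5′ end of the gene. This probe (chromosome 11, 69668633 to 69668692, mm9) read 0.64 ± 0.23 with doxycycline and -2.15 ± 0.40 with saline (SD, n = 4 each), a 6.92-fold difference (95% interval 4.86 to 9.85, limma adjusted p = 4.16e-04, exact permutation p = 0.0286). It was well above background on 4 of 4 doxycycline and 3 of 4 saline arrays. The second Tnk1 probe, toward the 3′ end (69664714 to 69664773), did not follow: it read 2.13 ± 0.23 against 2.58 ± 0.26, a log2 difference of -0.45 (SE 0.187, adjusted p = 0.136, exact permutation p = 0.0571). With array weights the 3′ difference passed the threshold as a decrease (-0.59, adjusted p = 0.0214), and averaging both probes gave a rise of 1.17 (adjusted p = 0.00502). Hprt, the purine salvage gene that carries the insertion, rose as well. Its probe (chromosome X, 50374757 to 50374816) read 4.34 ± 0.14 against -1.67 ± 0.58, a 64.6-fold difference (95% interval 42.0 to 99.4, adjusted p = 4.42e-05), with a log2 difference of 5.18 to 6.43 over the alternatives. Of 19 other housekeeping genes, 0 passed limma's threshold (4 at an unadjusted p under 0.05), with log2 differences from -0.42 to 0.51.

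**Figure D1:**
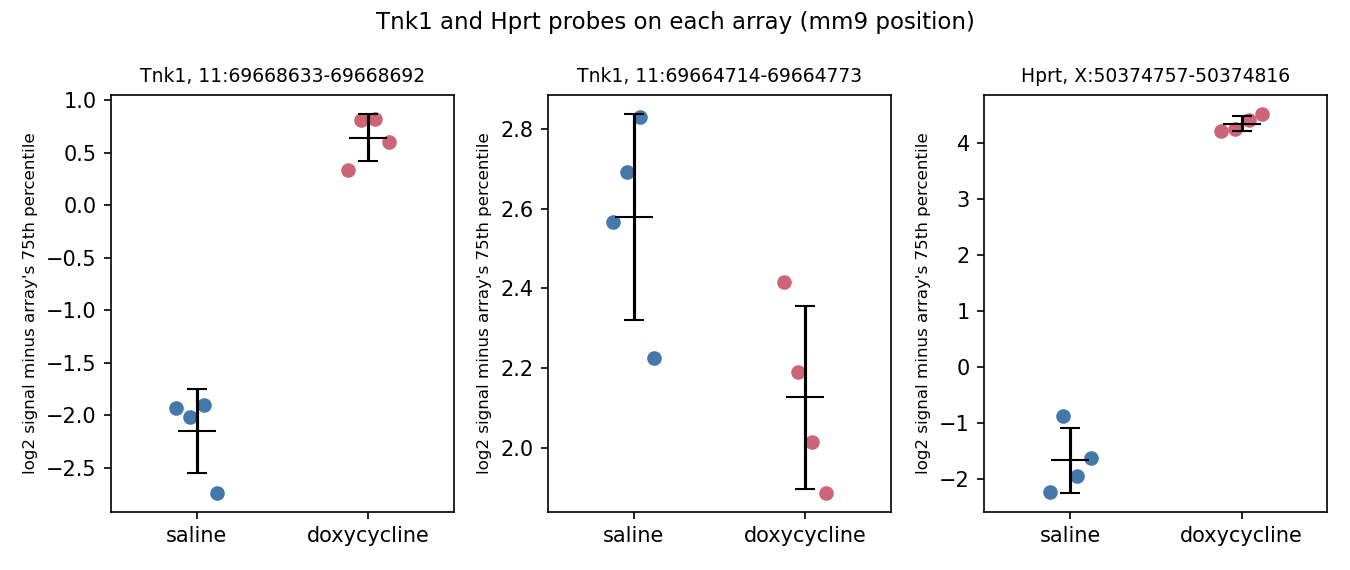
Level of the 2 Tnk1 probes and the Hprt probe on each of the 8 arrays, as log2 signal minus the array's 75th percentile, with mean and SD per group. All 4 doxycycline arrays lie above all 4 saline arrays for Hprt and the 5′-side Tnk1 probe, whose means differ by 6.01 and 2.79, and not for the 3′-side probe.

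Expression differed widely between the groups. Of 21362 genes tested, 1268 rose and 1687 fell with doxycycline, 810 and 809 of them by 2-fold or more. The groups did not overlap for 4673 genes (21.9%, against 2.86% by chance). Beside Hprt, the largest rises were those of the interferon-induced antiviral genes Mx1 (62.5-fold, SE 0.172 on the log2 scale, adjusted p = 1.62e-06) and Rsad2 (55.3-fold, SE 0.316, adjusted p = 1.11e-04). Other large rises were those of Glycam1, a mucin-like ligand of L-selectin (38.5-fold, or 62.9-fold without saline 2), Slfn4 (30.4-fold), Ifit2 (26.7-fold), the acute-phase serpin Serpina3n (24.4-fold), Gml (21.9-fold) and Chrdl2 (21.4-fold). Glycam1 and Chrdl2 were each well above background on 1 of 4 saline arrays and Slfn4 on 2 of 4, so the size of their folds is uncertain. The order of Hprt, Mx1, Rsad2 and Glycam1 depends on the setting, with log2 differences over the alternatives of 5.29 to 6.04 for Mx1, 5.57 to 6.0 for Rsad2 and 3.01 to 6.13 for Glycam1. Oxct2b, which the rule for names also takes, was not well above background on any saline array. It rose at least 4.77-fold, a bound that gives it no rank among the largest rises, and its call was lost with a common floor and with saline 2 and 4 both left out. The largest falls were Defb39, a beta-defensin (13.9-fold lower, log2 difference -3.79, SE 0.678, adjusted p = 0.00878), and the ceramidase Acer1 (12.5-fold, adjusted p = 3.70e-04). Rep15, Tppp, the arginase Arg2, the lectin Mbl2, endothelin 2 (Edn2), Proz, Odf3b and Akr1c14 fell by 9.90-fold to 11.8-fold. Defb39 was well above background on 1 of 4 doxycycline arrays. With a common floor its log2 difference was -0.895 and its call was lost, and with normexp background it was -1.30, so its rank as the largest fall holds only in part of the settings. Of these 19 genes without a bound, 17 had folds more than 1.5 times smaller with normexp background and 5 with a common floor (Tppp, Glycam1, Chrdl2, Defb39 and Mbl2). Mbl2 lost its call without doxycycline 3 or saline 1, 3 or 4 (highest adjusted p over its alternatives 0.104). The fall of Mbl2 was 11.4-fold, or 5.86-fold without doxycycline 2. Every named gene said to have risen or fallen had its 4 doxycycline values on a single side of its 4 saline values, except Ccr7 and Mlkl. Gene counts shrank by more than 1.5 times without doxycycline 3 (648 higher, 818 lower), doxycycline 4 (727 and 894), saline 1 (651 and 765) or saline 3 (652 and 729). Without saline 2 and 4 together 1090 genes were higher and 1027 lower, with array weights 2929 and 3400, and with no filter on dim probes 1850 and 11809.

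**Figure D2:**
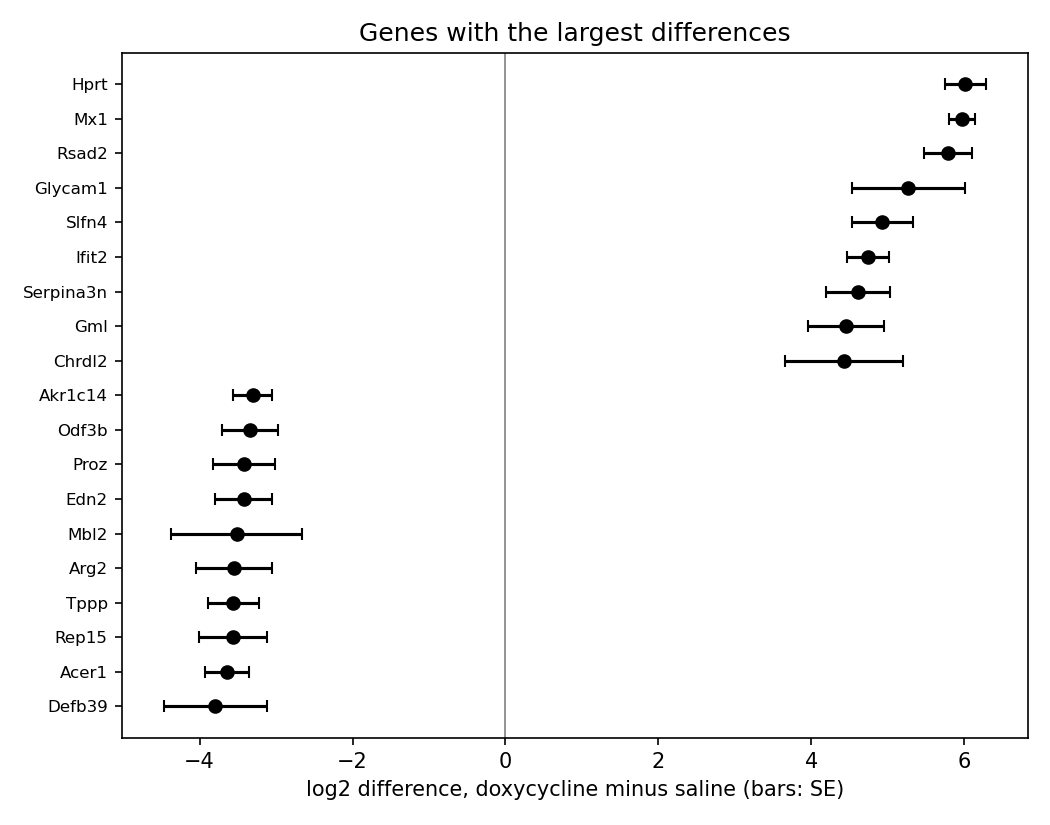
Log2 difference, doxycycline minus saline, of 9 named genes with the largest rise and 10 with the largest fall, with bars of 1 SE (n = 4 per group). Oxct2b, which has only a bound, is not drawn. Hprt and Mx1 lead the rises at 6.01 and 5.97, and Defb39 has the largest fall at -3.79.

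Antiviral interferon genes rose together. In the interferon-stimulated list, 24 of 34 tested genes rose and 0 fell (30 and 0 when adjusted over the list alone), with a median log2 difference of 2.08 (camera adjusted p = 8.74e-20, and adjusted p = 0.433 with an estimated correlation). Besides Mx1, Rsad2 and Ifit2, Herc6 rose 9.17-fold, with 2 of 4 saline arrays well above background. The list of interferon-gamma and antigen presentation genes split: 11 of 32 rose and 2 fell (12 and 3 when adjusted over the list alone), with a median of 0.11 (camera adjusted p = 0.00636, and adjusted p = 0.595 with an estimated correlation). The chemokine gene Cxcl10 rose 13.7-fold and the guanylate-binding protein genes Gbp2 and Gbp3 7.73-fold and 4.78-fold, while Ciita, the master activator of MHC class II genes, was 4.15-fold lower (log2 difference -2.05, adjusted p = 5.57e-04). Without saline 4 the interferon-gamma list missed the threshold (adjusted p = 0.0639).

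Inflammatory and injury genes rose as well. Of 21 acute-phase and cytokine signalling genes, 11 rose and 0 fell (17 and 0 when adjusted over the list alone), with a median of 1.73 (camera adjusted p = 7.66e-10, and adjusted p = 0.0875 with an estimated correlation). Lcn2, an iron-siderophore binding protein, rose 14.9-fold, the oncostatin M receptor Osmr rose 3.48-fold, and Il6 rose at least 2.31-fold with a saline signal not well above background, a call lost with a common floor. Lcn2 is also in the TNF and NF-kB, neutrophil, glucocorticoid and microbiota lists, and Il6 in the TNF and NF-kB list. The same rise thus counts in several lists. Among 23 epithelial alarmin and injury genes, 12 rose and 1 fell (16 and 1 when adjusted over the list alone; median 1.21, camera adjusted p = 8.28e-08, and adjusted p = 0.0875 with an estimated correlation). The epidermal growth factor receptor ligand Areg rose 10.6-fold, Ly6a 8.13-fold and the urokinase receptor Plaur 6.0-fold. Among 16 neutrophil genes 7 rose and 0 fell, the same counts as when adjusted over the list alone (median 0.71, camera adjusted p = 3.62e-05, and adjusted p = 0.0875 with an estimated correlation), with lactoferrin (Ltf) 7.11-fold and Hdc, which makes histamine, at least 6.37-fold higher (log2 difference 1.60, under that bound, with normexp background). Of 26 TNF and NF-kB targets, 9 rose and 1 fell (10 and 2 when adjusted over the list alone; median 0.65, camera adjusted p = 8.20e-04, and adjusted p = 0.595 with an estimated correlation), Cxcl5 by 9.52-fold and Ier3 by 2.24-fold.

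Genes that respond to glucocorticoids also rose. Of 20 tested, 13 rose and 1 fell (16 and 2 when adjusted over the list alone), with a median of 1.45 (camera adjusted p = 8.28e-08, and adjusted p = 0.0875 with an estimated correlation). The receptor co-chaperone Fkbp5 rose 5.60-fold, Zbtb16 12.4-fold and Tsc22d3 2.71-fold. Among 23 immediate early genes, 6 rose and 1 fell (9 and 1 when adjusted over the list alone; median 0.58, camera adjusted p = 0.0205, and adjusted p = 0.614 with an estimated correlation). The transcription factor gene Egr1 rose 6.17-fold and the phosphatase gene Dusp1 3.82-fold. The immediate early call was lost without doxycycline 2 (adjusted p = 0.0618) or saline 4 (adjusted p = 0.132). Of 20 microbiota-responsive epithelial genes, 5 rose and 0 fell, the same counts as when adjusted over the list alone (median 0.22, camera adjusted p = 0.0311, and adjusted p = 0.274 with an estimated correlation). Saa3 rose 8.91-fold, Retnlb 2.94-fold and Duoxa2 2.30-fold. Duoxa2 lost its call when its probes were averaged (adjusted p = 0.557), and the list lost its call without doxycycline 1, saline 3 or saline 4 (adjusted p = 0.0709, 0.0595 and 0.0613).

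The goblet cell, enteroendocrine and stem cell lists of the epithelium were lower. In the goblet cell list, 17 of 22 genes fell and 1 rose (18 and 1 when adjusted over the list alone), with a median of -1.40 (camera adjusted p = 1.55e-13, and adjusted p = 0.215 with an estimated correlation). The gel-forming mucin Muc2 was 3.93-fold lower (4.78 ± 0.16 against 6.76 ± 0.30, adjusted p = 5.57e-04), Ccl6 4.29-fold, Bcas1 5.61-fold and the kallikrein Klk1 6.49-fold lower. Klk1 belongs to a family of near-identical genes, and probes of such families can share signal, so its value is uncertain. Of 25 enteroendocrine genes, 9 fell and 0 rose (14 and 0 when adjusted over the list alone; median -0.98, camera adjusted p = 1.01e-06, and adjusted p = 0.215 with an estimated correlation), including secretin (Sct, 2.98-fold) and the granins Chga and Chgb (2.71-fold and 3.15-fold). In the stem cell list, 7 of 20 genes fell and 1 rose (11 and 1 when adjusted over the list alone; median -0.49, camera adjusted p = 0.00162, and adjusted p = 0.595 with an estimated correlation). The Wnt-responsive receptor Lgr5 was 2.83-fold, Ascl2 5.27-fold, Olfm4 3.20-fold and Axin2 2.99-fold lower. The 30 absorptive enterocyte genes held 0 calls in limma in either direction, also when adjusted over the list alone (8 at an unadjusted p under 0.05; median 0.09, camera adjusted p = 0.522). Of 29 junction genes, 3 fell and 0 rose, the same counts as when adjusted over the list alone (median -0.28, camera adjusted p = 0.0295, and adjusted p = 0.595 with an estimated correlation). The scaffold gene Tjp3 was 1.93-fold and the claudin Cldn15 3.99-fold lower, Cldn15 with its call lost when saline 2 and 4 were both left out (adjusted p = 0.0571). The junction call was lost without doxycycline 4 (adjusted p = 0.0782).

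**Figure D3:**
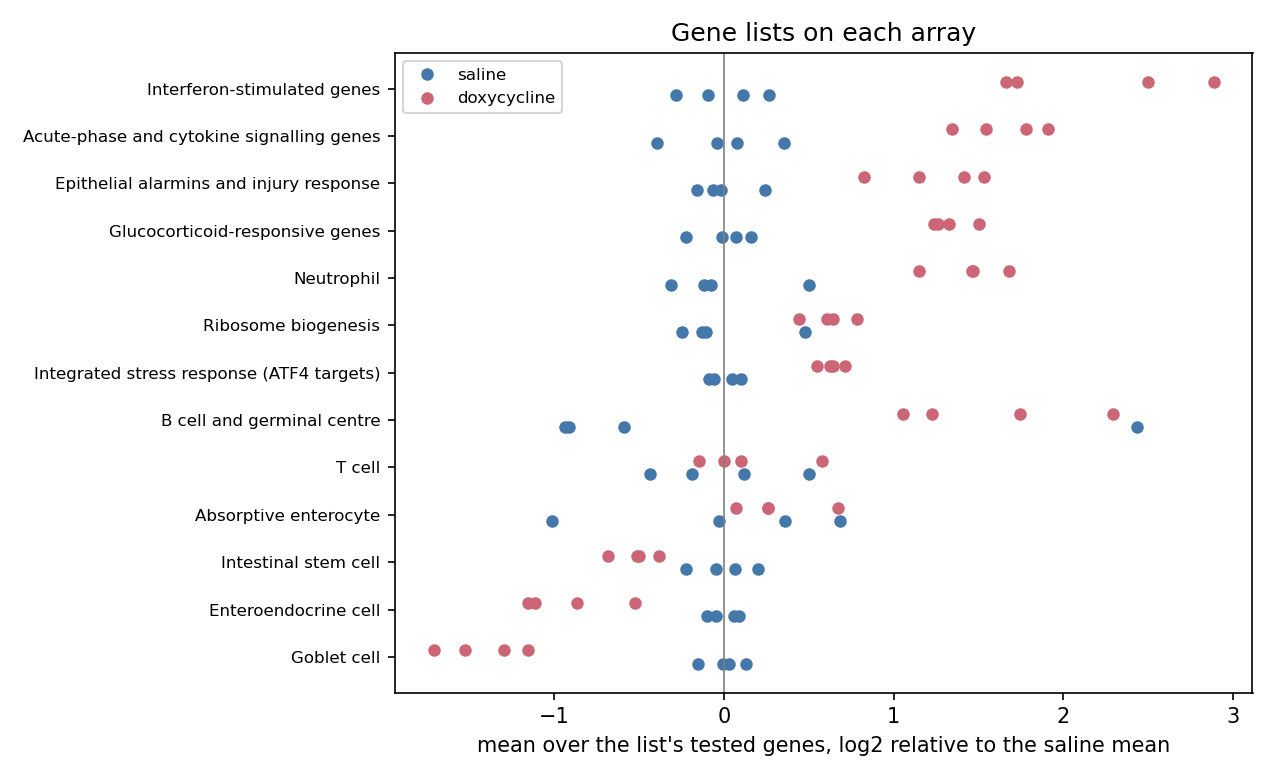
Mean over the tested genes of 13 lists on each array, in log2 units relative to the saline mean. Goblet cell genes lie at -1.71 to -1.15 on the 4 doxycycline arrays and interferon-stimulated genes at 1.66 to 2.88, while B cell genes on saline 2 (2.43) lie above all 4 doxycycline arrays.

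Metabolic genes moved in both directions. Of 35 ribosome biogenesis genes, 13 rose and 0 fell (24 and 1 when adjusted over the list alone), with a median of 0.67 (camera adjusted p = 6.44e-09, and adjusted p = 0.595 with an estimated correlation). The list means of the groups overlapped, with saline 4 at 0.48 and doxycycline 1 at 0.44 relative to the saline mean. Wdr12 rose 2.27-fold, with its call lost when its probes were averaged (adjusted p = 0.0649). Of 30 integrated stress response genes, 9 rose and 0 fell (9 and 1 when adjusted over the list alone; median 0.45, camera adjusted p = 6.80e-05, and adjusted p = 0.215 with an estimated correlation). The serine synthesis genes Psat1 and Phgdh rose 3.1-fold and 3.19-fold, and the stress cytokine Gdf15 rose 6.07-fold. The unfolded protein response list of 27 genes, from which the rule for names takes none, tended lower and missed the threshold (median -0.23, camera adjusted p = 0.10). It passed as lower with every kept probe by itself, without doxycycline 2 and without saline 2 (adjusted p = 0.0304, 0.0303 and 0.0254). Xenobiotic metabolism genes fell in 14 and rose in 4 of 38 cases (17 and 5 when adjusted over the list alone; median -0.75, camera adjusted p = 8.49e-04, and adjusted p = 0.595 with an estimated correlation). Cyp2c29 was 5.66-fold lower, whereas Cyp1b1 rose 2.88-fold. Cholesterol biosynthesis held 6 falls and 0 rises among 26 genes (7 and 0 when adjusted over the list alone; median -0.30, camera adjusted p = 0.00352, and adjusted p = 0.595 with an estimated correlation), with Tm7sf2 3.35-fold lower. Fatty acid synthesis held 4 falls and 1 rise among 20 (6 and 2 when adjusted over the list alone; median -0.99, camera adjusted p = 0.0168, and adjusted p = 0.595 with an estimated correlation), with Scd2 4.18-fold lower. Without saline 4 the fatty acid list missed the threshold (adjusted p = 0.0516).

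Mitochondrial genes showed small differences. Of 42 nuclear-encoded oxidative phosphorylation genes, 3 fell and 0 rose (0 and 0 when adjusted over the list alone), with a median of -0.40 (camera adjusted p = 1.44e-07, and adjusted p = 0.595 with an estimated correlation). The ATP synthase subunit Atp5e was 1.54-fold and the complex I subunit Ndufa1 1.53-fold lower. Atp5e lost its call when any of 5 single arrays was left out (highest adjusted p over its alternatives 0.0760), and Ndufa1 when any of 4 was (0.0833). The 44 mitochondrial ribosome genes had a median of -0.06 with 2 falls and 0 rises (0 and 0 when adjusted over the list alone; camera adjusted p = 0.435). The 20 mitochondrial chaperone and protease genes had a median of 0.06 with 0 calls in limma in either direction (0 when adjusted over the list alone, 2 at an unadjusted p under 0.05; camera adjusted p = 0.734). Doxycycline is known to inhibit mitochondrial translation, which transcript levels do not measure.

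Both cell death lists missed camera's threshold. Of 39 apoptosis genes, 7 rose and 2 fell, or 8 and 2 when adjusted over the list alone (median 0.06, camera adjusted p = 0.435). Fry gave an adjusted p of 0.00226 in the upward direction. Camera without the filter on dim probes gave an adjusted p of 0.00364, also upward. In that setting the list's mean was 0.059 and the median of all genes was -0.33. Camera sets a list against all other genes, so that pass does not show a rise of the list. The BH3-only gene Pmaip1 rose 4.0-fold and the TNF receptor Tnfrsf1a 1.63-fold, the latter with its call lost with the replicate block (adjusted p = 0.0577). Bcl2l11 was at least 1.33-fold higher and lost its call with normexp background, a common floor, and both saline 2 and 4 left out. In the necroptosis and pyroptosis list, 3 of 19 genes rose and 1 fell (4 and 3 when adjusted over the list alone). Its median was 0.12 and its mean -0.13, with an upward test (camera adjusted p = 0.933). Ripk3, a kinase of the necroptosis pathway, rose 2.21-fold (adjusted p = 0.00539). Its effector Mlkl was 2.41-fold higher (adjusted p = 0.0433), a call lost without any of 6 single arrays (highest adjusted p over its alternatives 0.117). The inflammasome gene Nlrp1b went the other way, 4.94-fold lower (adjusted p = 0.0219), a call lost without any of 4 single arrays (highest adjusted p over its alternatives 0.0808). Its relative Nlrp1a rose 1.52-fold, a call lost without any of 7 and with the replicate block. With the mean of its probes Nlrp1a turned to a log2 difference of -0.20 (limma adjusted p = 0.536). Of 24 p53 targets, 4 rose and 0 fell (5 and 0 when adjusted over the list alone; median 0.13, camera adjusted p = 0.0496, and adjusted p = 0.614 with an estimated correlation). Aen, a p53-induced nuclease, rose 2.38-fold. The p53 call was lost without doxycycline 3, doxycycline 4, saline 2, saline 3 or saline 4 (adjusted p = 0.116, 0.0962, 0.0820, 0.0595 and 0.0613).

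The ileum also holds immune, vascular and muscle cells, whose markers differed between groups. B cell and germinal centre genes had a median of 1.34, but 2 of 29 rose and 0 fell, the same counts as when adjusted over the list alone (camera adjusted p = 4.50e-05, and adjusted p = 0.639 with an estimated correlation). The list mean was 1.05 to 2.29 on the doxycycline arrays and 2.43 on saline 2, with the other saline arrays at -0.93 to -0.59, relative to the saline mean. Ly6d rose 8.63-fold, or 13.9-fold without saline 2. Endothelial and lymphatic genes rose in 4 and fell in 0 of 20 cases (9 and 1 when adjusted over the list alone; median 0.57, camera adjusted p = 7.82e-04, and adjusted p = 0.595 with an estimated correlation), with Tie1 at 3.44-fold and the lymphatic marker Lyve1 at 2.63-fold. Macrophage genes rose in 4 and fell in 1 of 22 cases (7 and 1 when adjusted over the list alone; median 0.69, camera adjusted p = 0.00633, and adjusted p = 0.595 with an estimated correlation), with the mannose receptor Mrc1 at 2.06-fold. That call was lost without saline 4 (adjusted p = 0.0569). Smooth muscle genes fell in 4 and rose in 0 of 23 cases (9 and 1 when adjusted over the list alone; median -0.51, camera adjusted p = 0.00256, and adjusted p = 0.614 with an estimated correlation), with Casq2 2.76-fold lower. Erythrocyte genes fell in 3 and rose in 0 of 10 cases (6 and 0 when adjusted over the list alone; median -1.53, camera adjusted p = 0.00225, and adjusted p = 0.595 with an estimated correlation), with the haem synthesis gene Alas2 4.63-fold lower, a call lost with saline 2 and 4 both left out (adjusted p = 0.0526).

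A further set of lists passed camera's test but lost their calls when single arrays were left out. Matrix genes rose in 5 and fell in 0 of 27 cases (6 and 0 when adjusted over the list alone; median 0.31, camera adjusted p = 0.0496, and adjusted p = 0.723 with an estimated correlation). The matrix metalloproteinase Mmp3, well above background on 1 of 4 saline arrays, rose 15.1-fold (log2 difference 3.91, and 2.03 with normexp background), and its inhibitor Timp1 5.97-fold. The matrix call was lost without doxycycline 2, doxycycline 4, saline 2 or saline 4 (adjusted p = 0.248, 0.0981, 0.10 and 0.156). Dendritic cell genes rose in 2 and fell in 0 of 14 cases, or 3 and 0 when adjusted over the list alone (median 0.65, camera adjusted p = 0.0304, and adjusted p = 0.595 with an estimated correlation). Their chemokine receptor Ccr7 was 7.80-fold higher, a call lost without any of 6 single arrays (highest adjusted p over its alternatives 0.0961), and 13.4-fold higher without saline 2. The dendritic call was lost without doxycycline 2, saline 3 or saline 4 (adjusted p = 0.0659, 0.0595 and 0.139). Mast cell and eosinophil genes rose in 3 and fell in 1 of 12 cases (4 and 1 when adjusted over the list alone; median 0.82, camera adjusted p = 0.0435, and adjusted p = 0.595 with an estimated correlation). The receptor Il5ra was at least 2.80-fold higher, with its call lost with a common floor. The receptor Kit, also on this list, was 2.11-fold lower, and which cells its fall belongs to was not tested. The mast cell call was lost without doxycycline 2, saline 3 or saline 4 (adjusted p = 0.0618, 0.0701 and 0.110). Of 42 mitosis genes, 0 passed limma's threshold, also when adjusted over the list alone (3 at an unadjusted p under 0.05; median 0.27, camera adjusted p = 0.0108, and adjusted p = 0.758 with an estimated correlation), and without saline 2 the list missed the threshold (adjusted p = 0.385). Of 38 DNA replication genes, 1 rose and 0 fell (0 and 0 when adjusted over the list alone; median 0.28, camera adjusted p = 0.0205, and adjusted p = 0.758 with an estimated correlation). Without doxycycline 2, doxycycline 4, saline 2 or saline 3 that list missed the threshold (adjusted p = 0.0618, 0.0576, 0.164 and 0.0597). Saline 4 had the highest list mean of all 8 arrays for mitosis and for DNA replication. It read 0.54 and 0.44 relative to the saline mean, against at most 0.42 and 0.35 on the doxycycline arrays.

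Of the 60 lists, 20 were higher and 10 lower with the preset correlation. With an estimated correlation the numbers were 0 and 0 (8 lists at an unadjusted p under 0.05), and with fry 13 and 10. At the preset correlation, other splits of the 8 arrays into 4 and 4 gave 9 to 29 lists past the threshold. Those with as many doxycycline as saline arrays on each side gave 9 to 23. The number of lists by itself therefore carries little weight. Beside the B cell, ribosome biogenesis and cell cycle lists, the array means of the groups also overlapped for 6 lists past the threshold. These were the xenobiotic, fatty acid, immediate early, macrophage, matrix and smooth muscle lists. Fry ended the calls of the fatty acid, immediate early, DNA replication, mitosis, matrix, B cell, macrophage, dendritic, mast cell and smooth muscle lists. It passed the apoptosis list as higher and the Wnt and Cajal cell lists as lower, which camera did not. Without the filter on dim probes 2 lists were lower, the goblet and enteroendocrine lists, and the calls of the other lower lists and of the mast cell list were lost. In that setting 8 lists passed that had missed the threshold, all with upward tests, among them the apoptosis, absorptive enterocyte (adjusted p = 0.00567) and mitochondrial chaperone lists (adjusted p = 0.0332). Camera sets a list against all other genes, and the median of all genes was -0.33 there, so an upward test need not mean that a list rose. The calls of cholesterol biosynthesis, junctions and mast cells were lost with normexp background, those of the p53, matrix and mast cell lists with quantile and with median scaling, and that of junctions with quantile scaling. A common floor, and probes well above background on all 8 arrays, ended the calls of junctions and mast cells. The mean of kept probes ended those of the p53, microbiota, matrix and mast cell lists, and every kept probe by itself those of the microbiota, matrix, dendritic and mast cell lists. The replicate block ended those of the p53 and matrix lists. Leaving out saline 2 and 4 ended those of the p53, interferon-gamma, microbiota, matrix and mast cell lists. In all, the mast cell call was lost in 14 of 23 settings. The arrays also differed in signal over background. Doxycycline arrays had 57.4% ± 0.938 of probe spots well above background and saline arrays 42.8% ± 1.76 (SD, n = 4 each, exact permutation p = 0.0286, or 0.0857 after Benjamini-Hochberg over 3 measures). The 75th percentile of signal was 355 ± 57.9 against 304 ± 55.8 (exact permutation p = 0.286, or 0.429 adjusted). The median signal of negative-control spots, a measure chosen after the arrays were seen, was 24.1 ± 0.994 against 37.5 ± 11 (exact permutation p = 0.0286, or 0.0381 after adjustment over 4 such measures). Of 2230 tested genes not well above background on any saline array, 338 rose. The genes tested held 0 that were not well above background on any doxycycline array, so a matching set of falls could not be seen. Among 16119 genes well above background on all 8 arrays, 790 rose and 1575 fell.

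**Figure D4:**
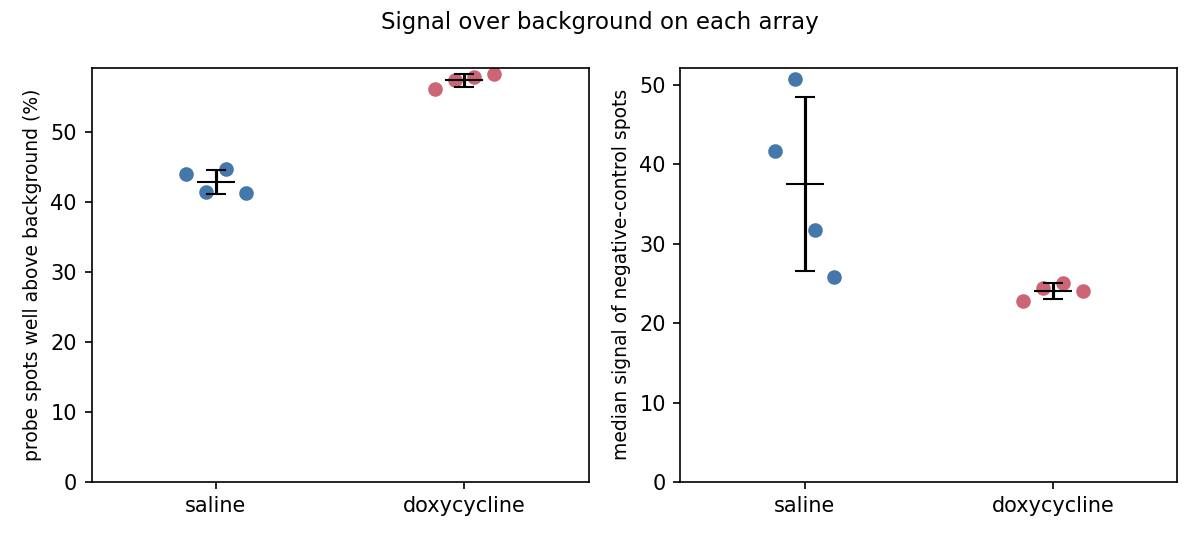
Percent of probe spots well above background (left) and median signal of negative-control spots (right) on each of the 8 arrays, with mean and SD per group. The 4 doxycycline arrays lie at 56.1% to 58.3% and the 4 saline arrays at 41.3% to 44.7%.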

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

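The comparison in this part was set before the data were examined, and no test here was chosen after its result. In each group of 4 arrays, the gap between the highest or lowest array and its nearest neighbour was divided by the group's whole range. Of 358 groups examined, 21 exceeded Dixon's 95% critical value, where chance flags about 1 in 20 groups (17.9 expected), so single entries carry little weight.

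Saline 2 stood apart most often. Its mean over the B cell and germinal centre list was 2.43, against -0.93 to -0.59 on the other saline arrays (ratio 0.897). The lymphoid chemokine receptor Ccr7 (0.893) was also highest there, as were Gml (0.987), Glycam1 (0.842), Fscn1 (0.902) and Dusp1 (0.957), while Ripk3 was lowest (0.917). Saline 4 was highest for Shmt2 (0.953), Aen (0.835), Ncl (0.933) and Orc6 (0.873), and lowest for Gata2 (0.855) and for the 5′-side Tnk1 probe (0.864, at -2.74 against -2.02 to -1.91). Saline 1 was highest for Mmp3 (0.852).

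Among the doxycycline arrays, doxycycline 1 was lowest for Mmp3 (0.940) and Col4a2 (0.847). Doxycycline 2 was highest for Esam (0.854) and Yme1l1 (0.916). Doxycycline 3 was lowest for Akr1c14 (0.858). Doxycycline 4 was lowest for Rrm2 (0.922) and Gata2 (0.836). No explanation was tested for these values.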

How the results depend on the processing

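The common floor and the joint removal of saline 2 and 4 were chosen after the data were seen, and all other settings were planned. Against 1268 higher and 1687 lower genes, counts moved by more than 1.5 times without the filter on dim probes (11809 lower, with 13.5% of calls higher against 42.9%), with array weights (2929 higher, 3400 lower), with the replicate number as a block (787 and 905), at adjusted p 0.10 (2185 and 2739) or 0.01 (403 and 488), and without saline 2 and 4 (1027 lower). Leaving out single arrays gave 648 to 1541 higher and 729 to 1870 lower genes, and 12 to 20 higher lists, with 12 in the absence of saline 4. Smaller shifts came from normexp background, with 1423 higher and 2373 lower genes and 2426 of the 2955 calls shared. Without the filter, the median of all genes moved to -0.33. That setting adds dim probes, and array weights change the spread used. For the other changes the cause was not tested, beyond fewer arrays entering the fit.

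The replicate numbers did not pair the arrays: same-numbered arrays had correlations of their deviations of 0.006, -0.044, 0.113 and 0.0125. With the replicate number as a block, 1568 calls were shared with the 2955, and 18 lists were higher and 11 lower.

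The 5′-side Tnk1 probe kept its direction and its call in each setting run, from 1.98 (normexp) to 2.89, and could not be tested among probes well above background on all 8 arrays. The 3′-side probe turned to 1.17 when both probes were averaged, since that mean holds the other probe, and passed the threshold at -0.59 with array weights. Nlrp1a turned to -0.20 with the mean of its probes, and Aurkb and Ttk turned to -0.011 and -0.019 with normexp. Lists lower fell to 2 without the filter. With an estimated correlation 0 lists were higher and 0 lower, and fry gave 13 higher. Among the lists that the rule for names takes, means where the test changed direction were 0.011 (normexp) and -0.074 (no filter) for the mitochondrial ribosome, -0.39 for tight junctions with no filter, and 0.060 for mast cells among probes well above background on all 8 arrays. For necroptosis they were -0.19 (mean of probes), -0.17 (every probe) and -0.21 (without saline 2 and 4). Leaving out single arrays gave -0.25 to -0.056 for necroptosis, -0.175 to 0.060 for Mitochondrial ribosome genes, and -0.041 to 0.165 for Mitochondrial chaperones and proteases. Of the 26 lists outside that rule, 18 changed direction in at least 1 setting, with 0 past the threshold in those settings or in the report (lowest adjusted p 0.0700). The cause of these turns was not tested. The lower signal over background of the saline arrays limits what can be said of dim genes, whose saline level is often only a bound.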

Other observations

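The tests of the labelled genotype, of T cell genes, of the B cell covariate and of doxycycline by itself were chosen after the values were seen, as were the common floor and the joint removal of saline 2 and 4. Several other fixed lists missed camera's threshold while single members changed, and the genes named in this part, except Hprt, Glycam1 and Ccr7, were chosen after their values were seen. In the list of genes for peroxisome proliferator-activated receptors and fatty acid oxidation, 5 of 32 genes rose and 4 fell (8 and 6 when adjusted over the list alone; median 0.0026, camera adjusted p = 0.858). Pdk4, which restrains pyruvate oxidation, rose by 2.71 on the log2 scale, and Acadm, an acyl-CoA dehydrogenase, fell by 1.21. Of 22 NRF2 targets, 4 rose and 0 fell (4 and 1 when adjusted over the list alone; median 0.041, camera adjusted p = 0.345), among them the haem oxygenase Hmox1 at 1.43. Among 20 genes of the proximal enterocyte, 6 fell and 1 rose (8 and 5 when adjusted over the list alone; median -0.81, camera adjusted p = 0.0966), with the iron exporter Slc40a1 at -2.0. Wnt targets held 4 falls and 0 rises among 20 (7 and 1 when adjusted over the list alone; median -0.29, camera adjusted p = 0.0782), all 4 of them also in the stem cell list.

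Of the other cell type lists, plasma cells had 4 falls and 1 rise among 15 genes (median -0.11, camera adjusted p = 0.345). T cells had 2 falls and 0 rises among 28 (median 0.19, adjusted p = 0.944), and Paneth cells 2 falls and 0 rises among 22 (median -0.11, adjusted p = 0.123). Adipocyte genes had a median of -0.74 (adjusted p = 0.0633) and read -3.10 on doxycycline 4 as a mean relative to saline. Fibroblast genes had a median of -0.05, a mean of 0.09 and a downward test (adjusted p = 0.831). Hypoxia genes had a median of -0.03, a mean of 0.0076 and an upward test (adjusted p = 0.857), and ileal bile acid genes a median of -0.05, a mean of 0.09 and an upward test (adjusted p = 0.944). In at least 1 alternative setting the fatty acid oxidation, NRF2, proximal enterocyte, Wnt, T cell, Paneth and adipocyte lists passed the threshold. The fatty acid oxidation and T cell lists did so only without the filter on dim probes, where the median of all genes was -0.33.

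Hprt was 6.01 higher (log2) on the doxycycline arrays. Another background, scaling or floor gave 5.18 to 6.05, and the 14 other tested genes within 1 Mb of its probe had a median difference of 0.0646, which argues against array background and against a change of the whole neighbourhood. The insertion lies at this locus. The 4 saline arrays carry a wild-type source name beside a transgenic strain, and read -2.23 to -0.88 for Hprt. No array of settled genotype shows what a locus without the insertion reads here. A change of the locus through induction and a difference in genotype therefore cannot be told apart.

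Among genes not well above background on all 8 arrays, 81.0% of 590 calls were higher with doxycycline. With normexp in place of the scanner software's background subtraction, 22.3% of 601 such calls were higher, so that subtraction is a candidate explanation. The filter on dim probes could not be weighed in the same way: without it 7.10% of calls were higher, but 87.0% of those 10382 calls were probes well above background on no array. The software replaces the values of spots that do not rise above the noise by surrogates. How many of these calls rest on surrogates was not counted. The filter's part and any true rise of dim genes therefore cannot be told apart here.

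The rise of interferon-stimulated genes was weighed against 3 explanations. The 31 listed genes well above background on all 8 arrays had a median of 2.07, which argues against dim signals. More lymphoid tissue in the doxycycline samples stays open. The 28 T cell genes had a median of 0.190 (quartiles -0.328 and 0.478), but B cell genes had a median of 1.34, and Glycam1 and Ccr7 were also higher. With the B cell mean of each array as a covariate, the 31 interferon genes kept a median of 2.07, with 16 past the threshold. That rests on saline 2, which had the highest B cell mean (2.43) and an interferon mean of -0.28: without it the median was 2.82 and 0 genes passed. Lymphoid tissue and other sources of the rise therefore cannot be told apart here. Doxycycline itself may act on these genes, and with 0 doxycycline arrays without the insertion, drug and induced gene cannot be told apart.

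For the number of genes the real split stood alone. Among the 35 splits of the 8 arrays into 4 and 4, 1 (the real split) gave 2955 genes, and the highest of the others gave 0. That argues against chance, at the smallest exact permutation p that these splits can give (0.0286). It does not part treatment from slide row, which coincide. For lists with the preset correlation, the real split gave 30, and the other splits gave 9 to 29 while calling 0 genes each. The split with 29 held doxycycline 1, 2 and 3 with saline 2. It keeps part of the treatment difference, so a margin of 1 list over it does not measure chance. Splits with as many doxycycline as saline arrays on each side gave 9 to 23. The real split gave the most lists of the 35, as it did for genes. Lists passed under every grouping, however, so their number does not show that any given list changed. With an estimated correlation 0 lists passed.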
